A study of Homo sapiens with 2 samples.

How the data were processed

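RNA was measured on 2 Affymetrix whole-transcript arrays. Each array held the total RNA of HEK293T cells, a human embryonic kidney line transformed with adenovirus sequences that also carries the SV40 large T antigen. Per the labels, 1 array came from cells grown in DMEM, a standard culture medium, and 1 from cells grown in DMEM lacking riboflavin (vitamin B2), both for 25 generations. RNA was extracted with a column kit that keeps small RNA, and biotin-labelled cDNA was hybridised, per the labels' protocols.

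The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console, per the labels. The log2 scale was read from the values, which ran from 1.79 to 14.5. RMA corrects background, brings the arrays to a common distribution and summarises the probes of a set. A change in the total amount of RNA per cell is therefore not visible, and small and dim differences are compressed. The version, the settings and the genome build are not given in the sources used here. The sorted values of the 2 columns differed by 0.016 on average and by 0.37 at most, so the columns were close to but not exactly at 1 distribution. Scanner files and detection calls were not used here.

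The table held 70523 probe sets. The platform annotation gave 1 gene symbol for 23781 of them and several symbols for 1543, and 45199 were not named here. Control and spike-in rows numbered 1498 and exon-level rows 1437. Both, and the probe sets with several symbols, stayed out of all comparisons of genes and lists. They are part of the values given for all probe sets or for whole columns. The 23781 probe sets made 22465 genes, of which 479 had over 1 probe set. A gene with several probe sets was taken at the one with the highest mean over both arrays. An Entrez ID was given for 20341 genes, and 20296 of these were found in a RefSeq gene table of assembly GRCh38.p14, which changed no symbol and served for gene classes and for the order of genes along chromosomes. No coordinates are printed because the build of the array design is not given.

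The quantity compared was the log2 difference per gene, without minus with riboflavin. There was 1 array per group and no technical replicate, so no test across genes was run and no p-value is given. A fixed size rule was used in place of a test. Genes were counted at 2-fold, and members of gene lists at 1.5-fold. No pseudocount was added. As a gauge of background, the 95th percentile of 394 olfactory receptor genes was taken on each array, which gave 4.73 with riboflavin and 4.64 without. A gene counted as above background when the higher of its 2 values reached the level of that array. Where the dimmer array lay under background, the fold is given as a lower bound against the background level of that array. The number of arrays limits the precision of all values.

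The median difference of each gene list was set against the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. The percentile describes these 2 arrays and is no test of the conditions, since genes of a pathway vary together and random lists do not. A list was called outside the range when its percentile was under 2.5 or over 97.5. There were 6 main lists and 28 further lists, with 853 entries, of which 732 matched a gene, 3 of them through an older symbol. The others had no probe set with that symbol alone. The list of mitochondrial genome transcripts had no such probe set and gives no value. In addition, 5 classes were read from the symbols.

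These lists, the size rules, the background rule, the alternatives and the naming rule were fixed before the data were examined, except where marked. A further 3 lists were added after patterns in the data were seen. They hold NF-kB genes, cytosolic aminoacyl-tRNA synthetases and mitochondrial ones, and are not counted among the lists above. Named are the 12 genes with the largest difference in each direction among those above background, without small or non-coding RNA, immune receptor segments and uncharacterised loci, all members of the riboflavin list, and in each list up to 4 members above background with at least a 1.5-fold difference. In a main list with fewer than 2 such members, its 2 members with the largest difference above background are named. Genes named outside this rule are marked as chosen after their values were seen.

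The list percentile and the size rule were tried on simulated data. These were independent normal values per gene, with the spread that genes of similar mean had on these arrays. Genes of a pathway vary together in the real data, and the spread includes any real differences. The rates below therefore describe the simulation and do not give the error rate of these data. Of 40 simulated lists of 25 genes with no shift, 2.5% fell outside the range, and 42.5%, 85.0% and 100% did at planted shifts of 0.1, 0.2 and 0.4. Among 15801 genes, the 2-fold rule recovered 3.0% of 200 genes changed by 0.58 on the log2 scale, which is under its limit. It recovered 48.5% of those changed by exactly 2-fold and 99.0% of those changed by 1.5 on the log2 scale. Unchanged genes counted were 2, 2 and 1. Alternatives were a loess trend subtracted (span 0.3), centring on the median, other filters on dim genes, the mean of all probe sets, other size rules, the dimmer array raised to its background (chosen after seeing the data), the mean in place of the median of a list, and random lists not matched on expression. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.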

Results

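Gene expression was compared between HEK293T cells kept in riboflavin-free medium and HEK293T cells kept in complete medium, in the context of proliferation and cell cycle genes. Each condition was represented by 1 array after 25 generations, so the differences have no replicate check and describe 2 arrays. The median over all probe sets was 4.65 with riboflavin and 4.64 without (log2 RMA value). The arrays correlated with r = 0.994 across all probe sets, which include control and unnamed rows, and with r = 0.9835 across the genes above background. Of 22465 genes, 15801 were above background, and 96.8% of these differed by less than 1.5-fold. Their differences had an SD of 0.25 on the log2 scale. Olfactory receptor genes, most of which are silent outside the nose, gave 95% of their differences between -0.35 and 0.37, and the largest among 394 was 1.60-fold.

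Without riboflavin, 49 genes were at least 2-fold higher and 11 at least 2-fold lower. Of these, 41 and 8 were protein-coding by their RefSeq class, a split chosen after seeing the data. Genes not found in the RefSeq table, such as ZC3H6 and C4B below, have no class there, so the others are not all non-coding. The counts were 43 and 8 when the dimmer array of a gene was raised to its background, a setting also chosen after seeing the data. The largest difference was in SLC7A11, the cystine/glutamate exchanger, whose log2 value was 7.66 with riboflavin and 10.12 without, 5.53-fold higher. NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, was 4.15-fold higher, from 7.66 to 9.71. TXNIP, which binds thioredoxin and limits glucose uptake, was 3.50-fold higher, from 5.90 to 7.71. CTH, the enzyme that makes cysteine from cystathionine, was 3.23-fold higher, ASNS, which makes asparagine, 3.18-fold, and ALDH1L2, a mitochondrial enzyme of folate metabolism, 3.02-fold. DDIT3, the stress transcription factor CHOP, was 2.91-fold higher. The small GTPase gene RAB39B was 3.80-fold higher, the cancer/testis antigen gene SAGE1 3.55-fold and ZC3H6 3.12-fold. TNFRSF9, a receptor of the TNF family, lay under background with riboflavin and was at least 2.85-fold higher. The probe set annotated to the complement gene C4B also lay under background with riboflavin and was at least 1.77-fold higher, but C4B has near-identical copies, so its value is uncertain.

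Among the genes that were lower without riboflavin, TFRC, the transferrin receptor that takes up iron, was 2.54-fold lower, from 9.18 to 7.83. DNAJA1, a cochaperone of HSP70, was 2.17-fold lower, the ephrin receptor EPHA7 2.14-fold, the splicing helicase DDX23 2.10-fold, the choline kinase CHKA 2.01-fold and the ribosomal protein gene RPL36AL 2.01-fold. KCTD12 was 1.99-fold lower, the glutamate transporter SLC1A3 1.96-fold and LPCAT1, an enzyme of phosphatidylcholine remodelling, 1.95-fold. The pseudogene TMSB4XP8 was 1.97-fold lower, and its probes may not tell it from its parent gene. PSMD5, a chaperone of proteasome assembly, and INA, a neuronal intermediate filament, lay under background without riboflavin and were at least 2.41-fold and at least 1.78-fold lower. The count of lower genes was 7 in place of 11 after centring the differences on their median.

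**Figure D1:**
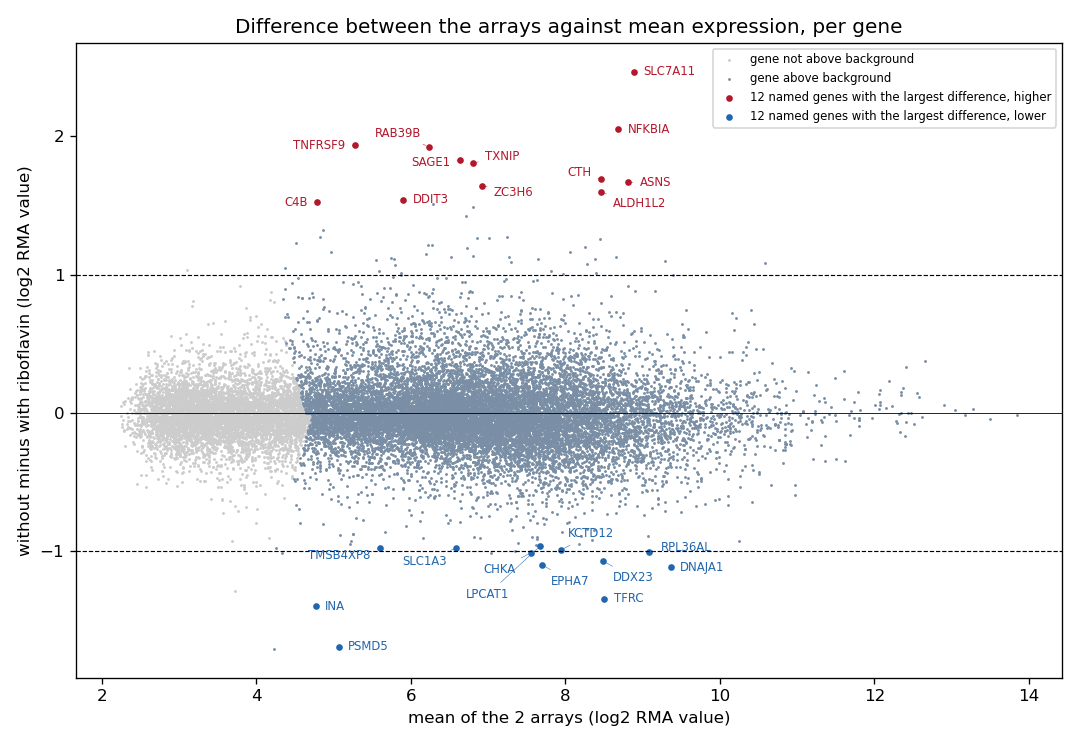
Difference between the arrays, without minus with riboflavin (log2 RMA value, y axis), against the mean of the 2 arrays (log2 RMA value, x axis). Each point is 1 of 22465 genes, dashed lines mark 2-fold, and the 12 named genes per direction are labelled at their deposited values, from which the differences of TNFRSF9, C4B, PSMD5 and INA, under background on 1 array, can be given only as lower bounds. Of the other labelled genes, SLC7A11 is highest at 2.47 and TFRC lowest at -1.34.

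The genes that handle riboflavin itself differed little between the arrays. RFK, the kinase that makes FMN from riboflavin, was lower by 0.31 on the log2 scale, with values of 7.45 with and 7.14 without riboflavin. The carrier SLC25A32, which is known to move folate and FAD into mitochondria, differed by -0.19, the plasma membrane riboflavin transporters SLC52A2 and SLC52A3 by -0.15 and -0.11, and FLAD1, which makes FAD from FMN, by 0.02. All 5 measured members lay within 1.5-fold, and their median of -0.15 was at the 14.3rd percentile of matched random lists.

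Most enzymes that carry FMN or FAD also lay within 1.5-fold. Among 26 mitochondrial flavoprotein dehydrogenases, 24 of them above background, 1 was at least 1.5-fold higher and none was lower by that much. This was ACAD11, an acyl-CoA dehydrogenase, with 7.83 with and 8.95 without riboflavin, 2.16-fold higher. The next largest difference was in ACADVL, the very long chain acyl-CoA dehydrogenase, at 0.33 on the log2 scale. The list median was 0.04, at the 92.2nd percentile. None of the 40 other flavoenzymes reached 1.5-fold, but only 29 of them were above background, and differences of dim genes are compressed. The largest differences were in ERO1B, an oxidase of the endoplasmic reticulum, at 0.48, and in SQLE, the squalene epoxidase of sterol synthesis, at -0.48, and the list median of 0.00 was at the 76.5th percentile. A list of the flavin-dependent demethylases and their partners had a median of 0.02, at the 77.1st percentile, with 1 of 12 members, the corepressor subunit PHF21A, 1.62-fold higher.

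Genes of G2 phase and mitosis were lower without riboflavin as a group. Of 31 measured, 5 were at least 1.5-fold lower, none was higher by that much, and 4 had a difference above 0. KIF20A, a kinesin of cytokinesis, was 1.89-fold lower, from 8.80 to 7.88. The mitotic kinase PLK1 was 1.59-fold lower, the CDK-binding protein CKS2 1.56-fold and the kinase AURKA 1.53-fold. The list median of -0.28 lay below all 10000 random lists, whose central 95% ran from -0.12 to 0.06. The list median of the DNA replication genes, at -0.04 and the 47.1st percentile, was inside the range, and none of its 30 members reached 1.5-fold.

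Drivers of the G1/S transition went both ways. Of 22, 1 was at least 1.5-fold lower and none was higher by that much. The exception was MYC, a transcription factor of growth, with 9.51 with and 8.90 without riboflavin, 1.53-fold lower. CCNE2, a cyclin of S phase entry, followed at -0.56 on the log2 scale. The list median of -0.07 was at the 26.2nd percentile. Of 24 CDK inhibitors and p53 targets, GADD45A, a gene of growth arrest and DNA damage, was 1.66-fold higher and SESN2, a leucine sensor that is also on the stress response list, 1.60-fold higher, and none was lower by that much. The median of that list was -0.03, at the 44.9th percentile. The replication-dependent histones, of which 10 of 19 could be named to 1 gene, had a median of 0.09, at the 96.6th percentile, and near-identical copies make their values uncertain. The absence of replicates means that a list median inside the range does not show that the list was unchanged.

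**Figure D2:**
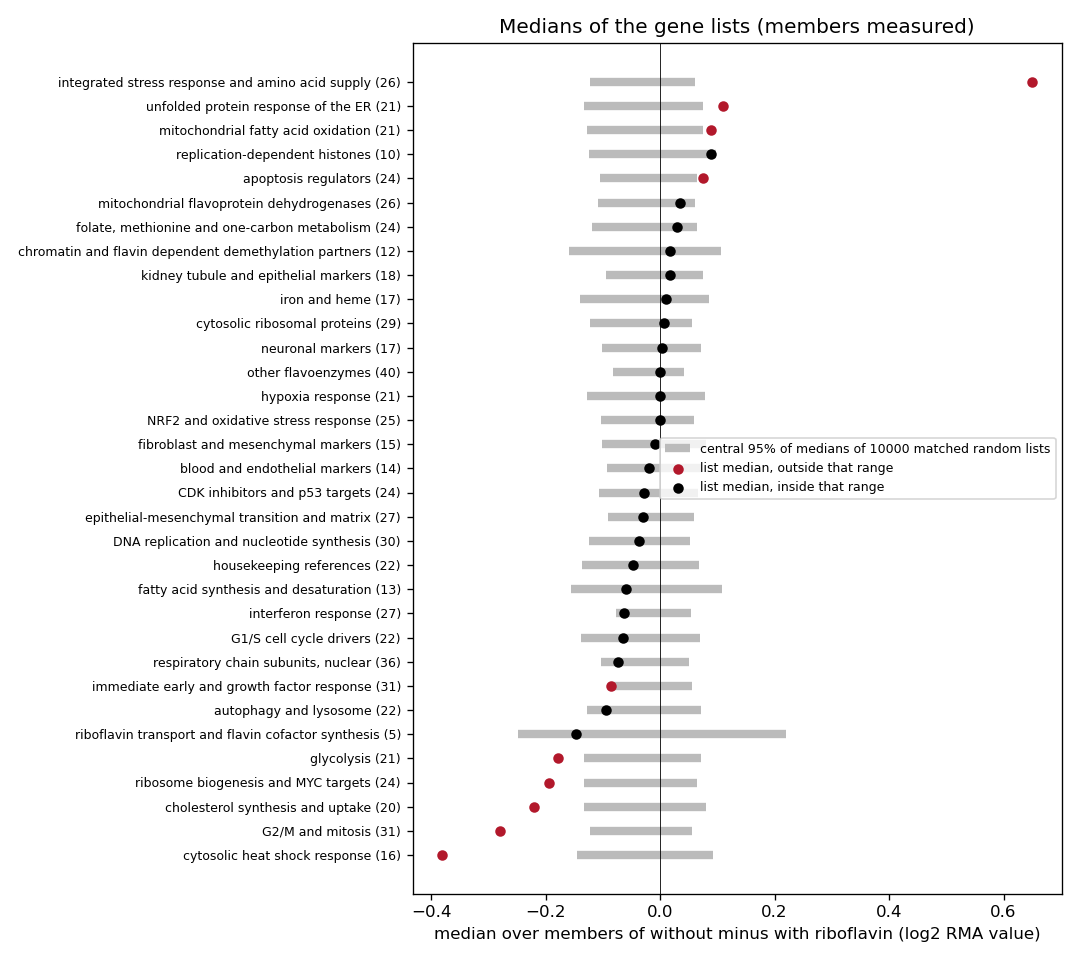
Median over the measured members (number in brackets) of the log2 difference without minus with riboflavin (x axis), for each gene list (y axis). Grey bars span the central 95% of the medians of 10000 matched random lists, and 10 of 33 lists lie outside theirs (red), the highest at 0.65 and the lowest at -0.38.

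Of 33 lists with a value, 10 lay outside the range, where 1.65 would if genes were independent. The widest shift was in the integrated stress response and amino acid supply, the genes that cells switch on through ATF4 when amino acids run short or other stress slows translation. Without riboflavin, 14 of its 26 members were at least 1.5-fold higher, none was lower by that much, and 25 had a difference above 0. FGF21, a secreted hormone named after its value was seen, lay under background with riboflavin and is not among the 14, since it was at least 1.10-fold higher. SLC7A11, CTH, ASNS and ALDH1L2, given above, had the largest differences. ATF4 itself, named after its value was seen, differed by -0.12. The list median was 0.65, or 0.62 with FGF21 at its bound, and 0.65 lay above all 10000 random lists, whose central 95% ran from -0.12 to 0.06. In the list of the endoplasmic reticulum's unfolded protein response, 4 of 21 members were at least 1.5-fold higher, none was lower by that much, and 12 had a difference above 0. HERPUD1, of protein degradation at that membrane, was 2.14-fold higher, the transcription factor XBP1 1.84-fold, the phosphatase subunit PPP1R15A 1.56-fold and the sensor ERN1 1.53-fold. That median was 0.11, at the 99.4th percentile.

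The cytosolic heat shock list was lower. Of 16 members, 5 were at least 1.5-fold lower and 1 had a difference above 0, and the median of -0.38 lay below all 10000 random lists. DNAJA1 is given above. HSPA1A, an inducible HSP70, was 1.85-fold lower, its cochaperone DNAJB1 1.72-fold and HSPE1, which acts in mitochondria, 1.61-fold. HSPA1A has a near-identical copy, so its value is uncertain. Of 20 genes of cholesterol synthesis and uptake, 4 were at least 1.5-fold lower and none was higher by that much. HMGCS1, an early enzyme of sterol synthesis, was 1.92-fold lower, from 7.85 to 6.91, INSIG1, a regulator of sterol sensing, 1.79-fold, and the thiolase ACAT2 and the sterol dehydrogenase NSDHL 1.54-fold each. The median was -0.22, at the 0.02nd percentile. Fatty acid synthesis had a median of -0.06, at the 30.1st percentile, with FASN, the fatty acid synthase, 1.85-fold lower and ME1, an NADPH-making malic enzyme, 1.51-fold higher.

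**Figure D3:**
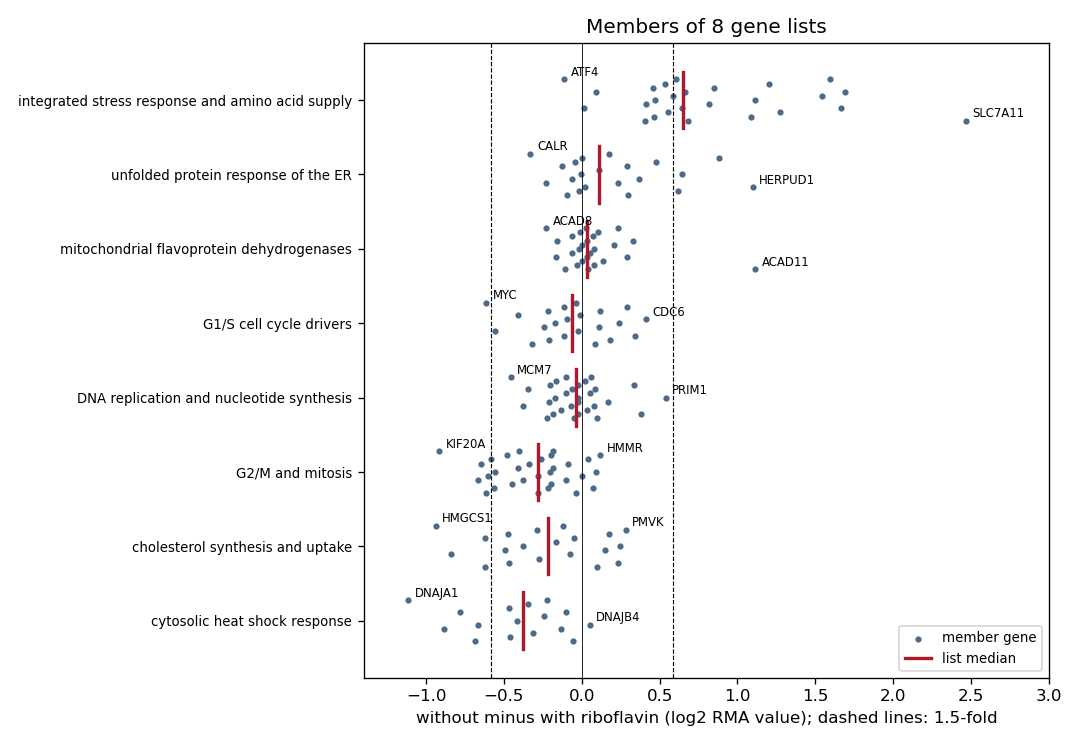
Log2 difference without minus with riboflavin (x axis) of each measured member of 8 gene lists (y axis), chosen after their values were seen, with the list median as a red bar and dashed lines at 1.5-fold. The members with the lowest and the highest difference are labelled, and the medians run from 0.65 in the integrated stress response to -0.38 in the heat shock list.

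Glycolysis genes were lower by small amounts. None of 21 reached 1.5-fold, 2 had a difference above 0, and the median of -0.18 was at the 0.34th percentile. Ribosome biogenesis and MYC targets had a median of -0.19, at the 0.06th percentile, with 1 of 24, the ribosome assembly gene NOP16, 1.51-fold lower. The 29 cytosolic ribosomal proteins had a median of 0.01, at the 82.9th percentile. Mitochondrial fatty acid oxidation had a median of 0.09, at the 98.5th percentile, with none of 21 members at 1.5-fold, and the mean of 0.09, at the 97.3rd, was inside the range. Respiratory chain subunits had a median of -0.07, at the 11.1th percentile, and a mean of -0.12, at the 0.42nd, which was outside the range. NDUFB3, of complex I, was 1.57-fold lower among 36.

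Oxidative stress genes of the NRF2 list had a median of 0.00, at the 66.0th percentile, and a mean of 0.12, at the 99.7th, with members on both sides. SLC7A11, which is shared with the stress response list, HMOX1, the heme oxygenase, at 1.77-fold, and ME1 were higher, and PRDX1, a peroxiredoxin, was 1.51-fold lower. The immediate early and growth factor list had a median of -0.09, at the 2.28th percentile, and a mean of -0.04, at the 17.96th and inside the range, with ATF3 2.17-fold and IER3 1.52-fold higher and none of 31 at least 1.5-fold lower. The 6 probe sets of IER3 differed by 0.34 to 0.60 on the log2 scale, and the printed fold is from the highest of these. Apoptosis regulators had a median of 0.07, at the 98.5th percentile, and a mean of 0.02, at the 68.2nd and inside the range. The cell death gene BCL2L11, the single member beyond 1.5-fold, was 1.58-fold lower. The hypoxia list had a median of 0.00, at the 71.6th percentile, with DDIT4 2.30-fold higher and NDRG1 1.51-fold lower. Folate, methionine and one-carbon metabolism had a median of 0.03, at the 89.99th percentile, with ALDH1L2 and the mitochondrial folate enzyme MTHFD2, 1.56-fold, higher and the methionine adenosyltransferase MAT2A 1.665-fold lower. ATF3, DDIT4, ALDH1L2 and MTHFD2 are also on the stress response list, so they are not separate signals. The iron and heme list had a median of 0.01, at the 76.7th percentile, with HMOX1 higher and TFRC lower. Autophagy and lysosome genes had a median of -0.09, at the 9.56th percentile, with the proton pump subunit ATP6V0D1 1.56-fold lower. Interferon response genes had a median of -0.06, at the 7.06th percentile, and the genes of epithelial-mesenchymal transition and matrix one of -0.03, at the 36.2nd, with no member of either list at 1.5-fold. In these 2 lists, 15 of 27 and 20 of 27 members were above background.

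The 4 lists of cell type markers gave no shift outside the range. Many of these markers were dim. Above background were 15 of 18 kidney tubule and epithelial, 11 of 17 neuronal, 8 of 15 fibroblast and 4 of 14 blood and endothelial markers. A median near 0 in mostly dim genes says little about those cell types. The kidney tubule and epithelial list had a median of 0.02, the neuronal list 0.00, the fibroblast list -0.01 and the blood and endothelial list -0.02, at the 76.6th, 71.8th, 46.0th and 39.9th percentiles. INA was the only marker in these 4 lists that was above background and at least 1.5-fold different. The housekeeping references had a median of -0.05, at the 36.2nd percentile, with TFRC as the 1 member of 22 beyond 1.5-fold. The mean differed in sign from the median in 6 of the lists. These were NRF2, given above, the CDK inhibitors and p53 targets with a mean of 0.06, iron and heme with -0.08, the neuronal list with -0.09, the kidney list with -0.01, and epithelial-mesenchymal transition and matrix with a mean of 0.0048, and all but the NRF2 mean were inside their range.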

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

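Beyond the named genes, the table held 42204 transcript clusters without a gene name here, which no comparison of genes or lists used, and some of them differed between the arrays. Of 15598 above background, 116 were at least 2-fold higher and 63 at least 2-fold lower without riboflavin, or 97 and 49 when the dimmer array was raised to its background. The largest was TC11002567.hg.1, with 5.10 with and 8.40 without riboflavin, a log2 difference of 3.29 that exceeds that of every named gene. TC08002311.hg.1 followed at 2.63. What these clusters transcribe was not determined.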

How the results depend on the processing

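The 72 values of named genes under other settings all kept their sign and moved by 0.04 at most on the log2 scale. This was fixed in advance. Each named gene had 1 probe set, centring moved all genes alike, and the loess trend lay between -0.042 and 0.008. The 36 values of the main lists under other settings all stayed on their side of the range. Centring cannot move the percentile of a list, so the centred values are no check, here or for the other lists. Of 210 values of other lists and classes, 198 kept their side, 7 moved into the range and 5 moved out of it. No list outside the range changed sign. Changes of sign were not counted for lists inside it, and some occurred. The median of long intergenic RNAs went from -0.0078 to 0.0175 among genes above background. Those that moved into it were immediate early genes (mean of the list, or all probe sets averaged), fatty acid oxidation (mean, or genes above background), apoptosis (mean) and the olfactory class. Those that moved out were NRF2, respiratory chain and one-carbon genes (mean) and, among genes above background, interferon genes and long intergenic RNAs. The count of genes at least 2-fold lower was 7 in place of 11 after centring on the median, 7 with both arrays above background and 7 with background at the 99th percentile of olfactory receptors. By their construction, 1.5-fold gave 330 higher and 181 lower, and 3-fold gave 10 higher and 2 lower. The share of higher genes among those counted was 81.7%, against 64.6% at 1.5-fold. The number of chromosomes outside the range was 5, and 2 with no filter on dim genes, and the cause was not tested. No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out. Scanner files were not used here, so signal over background could not be checked per probe.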

Other observations

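The single genes in this paragraph lie outside the fixed lists and were chosen after their values were seen. The arrestin-domain genes ARRDC3 and ARRDC4, relatives of TXNIP, were 2.85-fold and 1.95-fold higher without riboflavin. The amino acid transporters SLC43A1 and SLC1A4 were both 2.19-fold higher, and ASS1, of arginine synthesis, was 2.39-fold higher. PYROXD1, a flavin-dependent oxidoreductase, was 2.04-fold higher. The class of 1047 microRNA precursors had a median of -0.05, below all 10000 random lists, with 3 members at least 1.5-fold higher and 7 lower when the dimmer array was raised to its background. MIR221 and MIR222, which lie next to each other, differed by -0.995 and -0.858. Such probe sets read precursor or host transcripts, not mature microRNA. The 258 small nucleolar and Cajal body RNAs and the 543 long intergenic RNAs had a median of -0.01 each, inside the range. The olfactory receptors, of which 21 of 394 were above background, had a median of 0.0021, at the 99.99th percentile and outside the range, and a mean of 0.0033, at the 93.5th and inside it. Values were equal on both arrays in 919 genes (4.09%), and the upper end of the random range was 0.0000 in all 5 classes. A median just above 0 in mostly silent genes thus fell outside the range, which limits what the percentile of the microRNA class shows.

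For scaling or an intensity trend and for fewer cycling cells, the predictions below were written only after the result was seen. The loess setting itself was planned. The predictions of the others came before their values were known, for patterns already seen.

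The integrated stress response list was higher without riboflavin by a median of 0.65. An array-wide trend with mean expression was too small to account for this. The loess trend lay between -0.042 and 0.008, and the median was 0.68 after it was subtracted. RMA had already brought the arrays close to 1 distribution and the random lists were matched on expression. The outcome was therefore close to fixed in advance and is no separate check. Copy number of a few segments is argued against by 300 neighbouring genes of 15 members, FGF21 and the 14 at least 1.5-fold higher, which lie on 11 chromosomes and had a median of -0.0051. As a candidate explanation, an amino acid response would include the cytosolic aminoacyl-tRNA synthetases. The synthetase lists were added after the stress response pattern was seen, and SARS1 was left out. The 18 measured cytosolic synthetases had a median of 0.47, above all 10000 random lists. The 16 mitochondrial ones had 0.02, at the 79.9th percentile, and a mean of -0.025. The synthetase values do not tell a shortage of amino acids from other stress that acts through ATF4, which was not tested. Riboflavin depletion also cannot be told apart from another difference between the 2 cultures, such as density or medium age at harvest. The reason is that there was 1 array per group.

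The class of 534 zinc finger (ZNF) genes had a median of 0.12, above all 10000 random lists, with 34 members at least 1.5-fold higher when the dimmer array was raised to its background and none lower. The median was 0.11 with members at such bounds. ZNF585A and its close paralog ZNF585B, chosen after their values were seen, were 2.41-fold and 1.96-fold higher. The median was 0.14 after the loess trend was subtracted, which for the reason given above is no separate check. Gene length is argued against by random lists of other genes matched on genomic length and expression, whose medians centred on -0.015. Copy number of chromosome 19, which holds 246 of them, is argued against as the whole cause by a median of 0.080 in the 273 ZNF genes elsewhere, and by -0.05 in the 1205 other genes of that chromosome. The 246 ZNF genes on it had a larger median of 0.19, and at the deposited values 28 of them were at least 1.5-fold higher against 7 of the 273 elsewhere, so a part that is specific to chromosome 19 stays open. Probes shared between paralogs and a change in the silencing of these gene clusters remain open and were not tested.

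The G2/M list was lower by a median of -0.28. The median was -0.24 after the loess trend was subtracted, again no separate check. If fewer cycling cells were the whole cause, the DNA replication list should be lower too. Its median was -0.036, with a range of -0.12 to 0.03 when its members were resampled, above the G2/M median. The replication list thus did not share the size of the G2/M shift on these arrays. That range describes the spread among genes that vary together, not the spread between cultures. Whether replication genes would fall as far as G2/M genes with fewer cycling cells was not tested. The comparison therefore cannot decide this cause. Fewer cycling cells, a different spread of the cells over the cycle phases and regulation of mitotic genes remain open, as does the share of riboflavin in any of these.

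NFKBIA, TNFAIP3 and TNFRSF9 were all higher, TNFAIP3, chosen after its value was seen, by 2.81-fold. If targets of NF-kB were higher as a group, which is a hypothesis from these data, other such genes should be too. The 30 others measured, on a list of pathway genes and targets written after these 3 were seen, had a median of 0.17, above all 10000 random lists. Of the 30, 22 were above background, and 3 of these were at least 1.5-fold higher. The list median does not separate targets from components of the pathway. NFKB2 was 1.83-fold and CD83 1.63-fold higher, and 21 of the 30 had a difference above 0, while RELA, also named after its value was seen, differed by -0.07.

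Cultures kept apart for 25 generations could come to differ in copy number. No chromosome median was farther from 0 than -0.046, on chromosome 17, which argues against a whole-chromosome difference of over 0.2 in most cells. Of 557 windows of 50 neighbouring genes, 85 lay outside the central 95% of random lists, where chance would give 27.9 if genes were independent. Of the 85, 63 lay over the range and 22 under it, and windows overlap by 25 genes, so neighbouring ones share genes. The highest, at 0.28, lay on chromosome 19 between ZNF471 and ZNF324, in a ZNF gene cluster, and the lowest, at -0.12, on chromosome 17 between DOC2B and EMC6.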
